A study of Mus musculus with 5 samples.

How the data were processed

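The series measured poly(A) RNA from the retinas of mouse pups at postnatal day 7, in 3 control libraries and 2 libraries labelled Mettl14 cko. RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra kit, per the labels' protocols. The authors deposited 1 table of raw read counts per gene for 43432 Ensembl gene IDs, whole numbers with no normalization. The submitters' processing notes name CASAVA, HISAT2 and featureCounts and the genome build mm10; versions, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes cannot be told apart, and near-identical copies such as the gamma-crystallins and the globins may share or lose reads. No column of the table was left out.

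Gene symbols were taken from a table of gene names: 42462 IDs matched a symbol and 970 did not. Coordinates come from the GENCODE mouse annotation, release M21, on GRCm38, the assembly that mm10 denotes, and are 1-based; 42548 IDs had coordinates there. The group of each library comes from its title. Libraries were compared for double deposit by a chi-square of their counts over genes with at least 20 counts; the statistic per degree of freedom was at least 26.7 for every pair, so every library was kept as a sample of its own.

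Differences were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as factor (minimum count 10, minimum total 15), which left 17039; library sizes were scaled by TMM, and a quasi-likelihood F test (glmQLFit, glmQLFTest) compared the 2 groups with all 5 libraries and no covariate. P-values were adjusted by Benjamini-Hochberg over all genes tested and called at an adjusted p under 0.05. Fold changes are log2 of the libraries labelled cko over control; the standard error is the log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes; log2 CPM used a prior count of 2. The biological coefficient of variation was 0.216. The total count per library, 24315693 to 27100918, differed little, so depth was similar in both groups.

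The 27 gene lists (438 genes, 19 main lists of retinal cell types, m6A genes, cell cycle and stress responses and 8 check lists of other cell types and tissues) were tested with camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera's p-values were adjusted over the 27 lists. Members were also counted after adjustment over the list alone. The groups, the test, the covariates, the lists, the rule for named genes and the first set of other settings were fixed before the data were examined.

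The named genes follow this rule: the m6A writer list; the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and groups that do not overlap, passing over unnamed or predicted genes (Gm, Rik, LOC); for each main list the 2 called members with the smallest p in the direction most called members moved and the 1 with the smallest p in the other direction, or, where none was called, the member with the highest mean CPM; and for each check list the member with the highest mean CPM. BC030499 was at first passed over as a clone-type symbol; the patterns the rule lists do not cover it, and this was corrected after its values had been seen. Other genes were named after their values had been seen, among them Ythdf2, Fto, Alkbh5, Crygn, Bfsp1, Bfsp2, Mip, Pde6a, Slc24a1, Slc17a7, Cplx3, Unc13b, Nupr1, Rtp4, Eda2r, Ttr, Stra6, the collagen genes, the other globin genes, Slc4a1, Alas2, Tnnt3, Scgn, Dapl1, Kdr, Pax2, Rdh5, Usp18 and the DESeq2 calls of the closing section. Some genes are not reported here.

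The settings tried in that first set were DESeq2's size factors, upper-quartile factors or library totals in place of TMM; no low-count filter, or a CPM of at least 1 in at least 2 libraries; DESeq2 1.42.0 with its own filtering (26716 genes with a p, 16195 with an adjusted p), limma-voom or robust edgeR in place of the main test; each library left out in turn; the letter of the title as a replicate block; an adjusted p under 0.01; and the other list tests. Another 4 were chosen after seeing the data: DESeq2 on the genes kept for edgeR, the sex read from Xist and Y-linked genes as a covariate, removal of the genes of other tissues and all crystallins, and removal of a smooth trend of each library on GC content and transcript length.

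The edgeR, DESeq2 and list steps were tested in 5 simulations, built on the real means, library sizes and dispersions of the 17039 genes of this comparison. Each changed 200 genes, taken only from those with a mean of at least 1 CPM, and raised a further list 2-fold. EdgeR recovered 43.6% of genes changed 2-fold and 97.2% of those changed 4-fold, with 6.5% of its calls false; DESeq2, run on the same genes, recovered 53.6% and 98%, with 10.9% of its calls false. The list raised 2-fold was called by camera in 5 of 5 simulations, and 0 of 130 unchanged lists were called. Genes were simulated independently, so this does not test camera on correlated members. Estimated correlations in the real lists reached 0.90 (blood). The motif calculation of the closing section returned a correlation of 0.1, planted in random values and not in counts, as 0.094 to 0.103. This checks the calculation only, not its use on fold changes.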

Results

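Poly(A) RNA was sequenced from the retinas of mouse pups at postnatal day 7. The labels form 2 groups: 3 control libraries (a, b and c) and 2 libraries labelled Mettl14 cko (a and b). The abbreviation cko commonly stands for conditional knockout, and the labels used here name no allele or driver line. The name of the deposited table carries the gene symbol Six3 and an abbreviation that may stand for Mettl3 with Mettl14; the labels explain neither, so whether Mettl3 was targeted too is not settled here. The series title names Mettl14 and Mettl3 as joint regulators of retinal development, and the comparison asks which transcripts differed between the groups. Total gene counts were 26503943, 27100918 and 24315693 in control a, b and c, and 25912136 and 26513127 in the libraries labelled Mettl14 cko a and b. The labels do not say that the libraries came from separate animals. Read from sex-linked genes, each group held female and male libraries (below), so its spread is not technical alone. Control a and b both read as female, and whether they are separate animals is not given. The p-values measure only the spread between these samples.

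Mettl14, the RNA-binding partner of the methyltransferase Mettl3 in the complex that writes N6-methyladenosine (m6A) on messenger RNA, was not lower in the libraries labelled Mettl14 cko. Its level was 41.5, 46.7 and 38.7 CPM (read counts scaled to a common library size) in control a, b and c, against 55.6 and 44.8 CPM in the libraries labelled cko a and b. The log2 fold change was 0.25 (SE 0.20; edgeR adjusted p = 0.640), and its 95% interval ran from -0.20 to 0.69, a fold of 0.872 to 1.61. The gene lies on chromosome 3 from 123368297 to 123386108 (ENSMUSG00000028114, protein-coding). The count covers the whole gene, so a deletion of some exons that leaves the rest of the transcript in place was not measured. Because no fall was measured for the gene named in the label, every direction below is that of the libraries labelled cko, not of a measured loss of Mettl14.

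Among the other writers, Wtap, the adaptor that holds the complex in nuclear speckles, was at 171 CPM ± 15.8 (SD, n = 2) against 114 ± 14.9 (SD, n = 3) in the controls. Virma was at 127 against 88.3 CPM and Zc3h13 at 86.3 against 62.5 CPM. The catalytic subunit Mettl3 (chromosome 14, 52294841 to 52305128) was at 58.8 against 69.9 CPM, a log2 fold change of -0.25 (SE 0.19; edgeR adjusted p = 0.615). Rbm15, Rbm15b and Cbll1 had log2 values of 0.34, -0.14 and 0.30. None of the 8 members of the writer list passed edgeR over all genes tested, and 0 passed when adjusted over the list alone; 3 had an unadjusted p under 0.05, and 0 passed with DESeq2 or limma-voom. As a list they stood above other genes by camera (median log2 0.32, adjusted p = 0.0478), but not with an estimated correlation (adjusted p = 0.493). The camera call was also lost without control a (adjusted p = 0.0954), without control b (adjusted p = 0.0708) and without the library labelled cko b (adjusted p = 0.266), and under other settings, among them removal of a GC and length trend (adjusted p = 0.151), with medians of 0.29, 0.40, 0.24 and 0.26 in these 4.

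**Figure D1:**
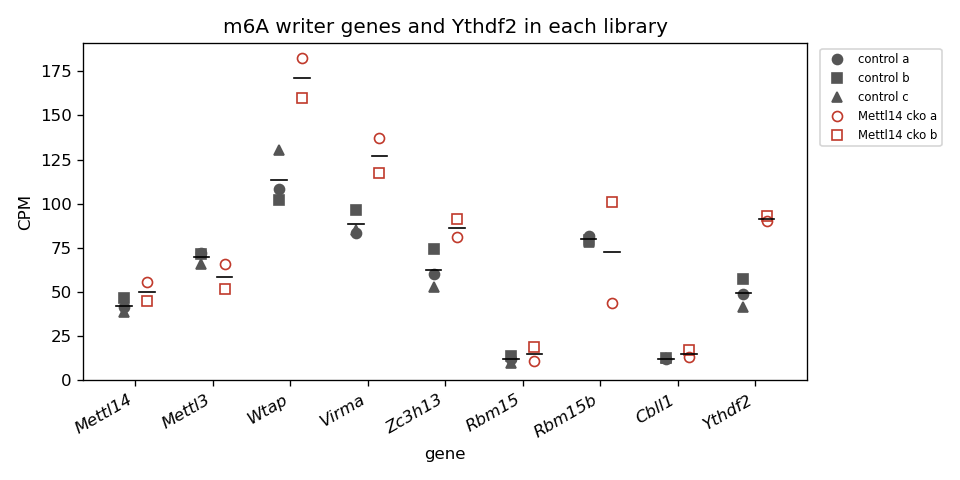
CPM (scaled read counts, linear axis) of the 8 m6A writer genes and the reader Ythdf2 in each of the 5 libraries; filled grey symbols are controls, open red symbols are libraries labelled Mettl14 cko, and short bars are group means. Mettl14 reads 38.7 to 46.7 CPM in the controls and 44.8 and 55.6 CPM in the libraries labelled cko, while Ythdf2 reads 90.0 and 92.8 CPM against at most 57.6 CPM in the controls.

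Of the 12 eraser and reader genes, Ythdf2, a cytoplasmic reader that directs m6A-marked transcripts to decay, had the clearest difference. It was at 91.4 CPM ± 1.97 (SD, n = 2) against 49.4 ± 8.04 (SD, n = 3), a log2 fold change of 0.89 (SE 0.20). Its edgeR adjusted p was 0.286 over all genes, while DESeq2 called it over all genes (adjusted p = 0.0299), as did edgeR with no low-count filter (0.0154). The unfiltered fit gave Ythdf2 about the same log2 (0.88). It called 262 genes in all against 17 in the main fit, so its calls, here and below, are not separate support. Ythdf2 was the 1 member that passed, upward, when adjusted over the list alone. The demethylases Fto and Alkbh5 had log2 values of -0.19 and -0.28, and Hnrnpa2b1, the most abundant member, 0.05. The list stood above other genes by camera (median 0.22, adjusted p = 0.0301), with an adjusted p = 0.493 with an estimated correlation. The call was lost without control a (adjusted p = 0.0925) and without the library labelled cko b (adjusted p = 0.223), with sex as a covariate (0.0559) and with the GC and length trend removed (0.198); the medians were 0.18, 0.18, 0.22 and 0.17.

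Lens genes made up nearly all of the differences that passed edgeR's test, and a smaller part of those called by DESeq2. Of 17039 genes tested, 17 passed edgeR at an adjusted p under 0.05: 16 fell in the libraries labelled cko and 1 rose. Of the 16, 15 belonged to the lens list and the other, Crygn, is also a crystallin-family gene; all 17 had an absolute log2 fold change of at least 1. The crystallins are the main soluble proteins of the lens, and Cryaa, the most abundant of them here, was at 489 CPM ± 206 (SD, n = 3) in the controls and 22.1 ± 18.4 (SD, n = 2) in the libraries labelled cko (log2 -4.47, SE 0.56; edgeR adjusted p = 0.00939). Among called genes with a mean of at least 5 CPM in the higher group, the largest fall was that of Crybb1 (chromosome 5, 112255815 to 112269585), from 181 to 6.28 CPM, a 28.9-fold difference (log2 -4.86, SE 0.50; edgeR adjusted p = 0.00623).

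The gamma-crystallin genes Crygc, Crygd, Crygf, Cryga and Cryge, which lie on chromosome 1 between 65048554 and 65928307, followed, with log2 values of -4.85, -4.71, -4.69, -4.65 and -4.65. These genes are near-identical copies, so the split of reads among them is uncertain. The lens list had 21 members tested, of which 15 fell over all genes and 20 fell when adjusted over the list alone. The lens fibre filament genes Bfsp1 (log2 -4.35) and Bfsp2 (-2.50) and the lens aquaporin Mip (-2.49) lay on the same side, and Bfsp1 passed over all genes. The median of the list was -4.18 (camera adjusted p = 8.3e-97; adjusted p = 0.197 with an estimated correlation). The lens list held 0.151%, 0.120% and 0.245% of all counts in control a, b and c, against 0.0128% and 0.00470% in the libraries labelled cko a and b. Without the library labelled cko b, edgeR called 0 genes (2210 at an unadjusted p under 0.05), and the lowest adjusted p of a crystallin was 0.0584, with log2 values of -3.80 for Cryaa and -4.30 for Crybb1; without control b it called 45, of which 19 were lens list or crystallin genes. With the sex read from the data as a covariate 9 genes were called, and Cryaa had a log2 of -4.50 and an adjusted p of 0.0705. On all 5 libraries limma-voom called 16 genes, and DESeq2 called 85 with its own filtering and 91 on the genes kept for edgeR. Lens list or crystallin genes were 16 of the 16 called by limma-voom, and 19 of the calls in each DESeq2 run.

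**Figure D2:**
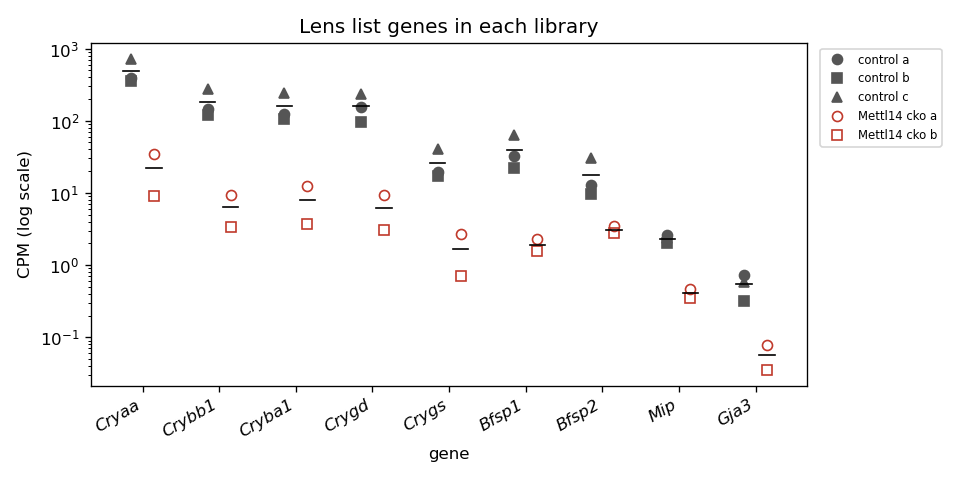
CPM (scaled read counts, log axis) of 9 lens list genes in each of the 5 libraries; filled grey symbols are controls, open red symbols are libraries labelled Mettl14 cko, and short bars are group means. For each of these genes both libraries labelled cko lie below all 3 controls; Cryaa reads 35.1 and 9.10 CPM against 350 to 726 CPM.

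Lists of genes of other tissues around the retina were also lower by camera, with controls that differed widely from each other. Alpha- and beta-globin transcripts were lower, with Hba-a1 at 34.1 CPM ± 24.7 (SD, n = 2) against 160 ± 73.2 (SD, n = 3), a log2 fold change of -2.23 (SE 0.50; edgeR adjusted p = 0.299). Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical pairs whose reads may be shared. The blood list (6 tested) had 0 members past edgeR over all genes (6 at an unadjusted p under 0.05; DESeq2 called Slc4a1 and Alas2) and 6 that fell when adjusted over the list alone; its median was -1.93 (camera adjusted p = 9.9e-12; adjusted p = 0.467 with an estimated correlation). Skeletal muscle genes, among them Acta1 (log2 -1.96, SE 0.57), had a median of -1.50 (camera adjusted p = 7.2e-06; adjusted p = 0.494 with an estimated correlation), and 6 of 7 fell when adjusted over the list alone. Pigment epithelium genes had a median of -0.68 (camera adjusted p = 4.0e-05; adjusted p = 0.723 with an estimated correlation), and Pmel, Ttr and Stra6 fell when adjusted over the list alone; Pmel, a melanosome matrix gene, had a log2 value of -1.24 (SE 0.34). Connective tissue genes had a median of -0.51 (camera adjusted p = 0.0170; adjusted p = 0.723 with an estimated correlation), and Col1a1, Col1a2 and Col3a1 fell when adjusted over the list alone. In these last 3 lists edgeR called 0 members over all genes, with 6, 5 and 3 at an unadjusted p under 0.05; DESeq2 called Myl1, Mylpf, Tnnt3, Pmel and Col1a2. Without control a edgeR called Hba-a1, Slc4a1, Tnnt3 and Col1a1 over all genes (adjusted p = 0.0215, 0.0227, 0.0272 and 0.0289), and without control b it called Tnnt3 (0.0435). The connective tissue call was lost without control c (adjusted p = 0.132), without the library labelled cko a (adjusted p = 0.0565) and without the library labelled cko b (adjusted p = 0.0953), with limma-voom (0.0543, median -0.52) and with the GC and length trend removed (0.0511, median -0.62). With no low-count filter edgeR called all 6 blood genes (Hba-a1 adjusted p = 5.2e-17) and the muscle genes Acta1 (1.1e-07), Myl1, Mylpf and Tnnt3. It also called the pigment epithelium genes Pmel, Ttr, Stra6 and Rdh5, and Col1a1, Col1a2 and Col3a1. The log2 of Hba-a1 was -2.24 there, about the same as with the filter. Calls over all genes went from 17 to 262 in that setting, so its calls depend on which genes enter the fit and not on larger differences. Control c was the highest of the 5 libraries in each of these lists, the lens list included. Control a was the lowest control in the blood, muscle, connective tissue and pigment epithelium lists, with mean log2 differences from the control mean of -0.90, -0.71, -0.70 and -0.33. The libraries labelled cko a and b were at -1.41 and -2.71 for blood, -1.31 and -1.57 for muscle and -0.51 and -0.69 for pigment epithelium. For connective tissue they were at -0.88 and -0.66, so control a lay between them and the groups overlapped. Without control c the medians were -0.37 for pigment epithelium, -0.97 for skeletal muscle and -0.16 for connective tissue genes. Without control a they were -0.89, -1.76 and -0.68. The connective tissue median was -0.59 without the library labelled cko b and -1.10 without cko a, where that of blood was -3.04.

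The 1 gene that rose was BC030499, at 6.59 CPM ± 3.25 (SD, n = 2) against 0.907 ± 0.430 (SD, n = 3), a 7.15-fold difference (log2 2.84, SE 0.43; edgeR adjusted p = 0.0380). It is a protein-coding gene on chromosome 11 from 78290841 to 78296805. The call was lost without control a (adjusted p = 0.0704), without control c (0.0878) and without the library labelled cko b (0.137), and with library totals (0.201), the stricter filter (0.0555), limma-voom (0.0771) or the sex covariate (0.277). Its log2 was 2.88, 2.51 and 2.22 without these libraries and 2.90, 2.84, 2.85 and 2.82 with the other settings. With the lens and other tissue genes removed before testing, an alternative chosen after seeing the data, its log2 stayed at 2.84 but its adjusted p was 0.352; edgeR then called 0 genes, with 1820 at an unadjusted p under 0.05.

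No retinal cell type list passed camera after the low-count filter with all 5 libraries and no covariate, and no member of one passed edgeR over all genes after the low-count filter; DESeq2 called 1 member, Slc24a1 of the rod list (adjusted p = 0.0445, and 0.0443 on the genes kept for edgeR). Among rod genes Sag, the rod arrestin, was at 2675 CPM ± 878 (SD, n = 2) against 4255 ± 1142 (SD, n = 3; log2 -0.67, SE 0.32; edgeR adjusted p = 0.470). In the rod list, Pde6a (log2 0.71) and Slc24a1 (0.84), which act in phototransduction and in calcium exchange of the outer segment, rose when adjusted over the list alone. The rod list had a median of -0.08 and a mean of -0.02, with camera's direction upward (adjusted p = 0.963). Its median was -0.23 without the library labelled cko a and 0.21 without cko b, each with 1 library left in that group. Without control c the median was 0.01. The cone list had a median of 0.13 (camera adjusted p = 0.404), which was 0.02 without the library labelled cko a, and its most abundant member Gnb3 was at 671 against 694 CPM.

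In the photoreceptor ribbon synapse list (median 0.07, camera adjusted p = 0.491), the members differed in direction. Slc17a7, the vesicular glutamate transporter of photoreceptors and bipolar cells, and Cplx3, a complexin of ribbon synapses, fell when adjusted over the list alone (log2 -0.70 and -0.81). Unc13b, a vesicle priming factor, rose (log2 0.91) by the same adjustment, at 292 CPM ± 23.1 (SD, n = 2) against 155 ± 43.3 (SD, n = 3). Over all genes their edgeR adjusted p were 0.433, 0.430 and 0.377; Unc13b was called without control b (log2 1.17, adjusted p = 0.0424) and with no low-count filter (0.00848). The list's median was -0.02 without control b.

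Bipolar cell genes had a median of -0.12 (camera adjusted p = 0.491), amacrine genes 0.10 (0.448), horizontal cell genes 0.17 (0.287), ganglion cell genes -0.32 (0.0913) and Muller glia genes 0.06 (0.749). In each of these lists 0 members passed edgeR over all genes and 0 when adjusted over the list alone, with 7, 3, 0, 3 and 2 members at an unadjusted p under 0.05; DESeq2 and limma-voom also called 0 of their members, while edgeR with no low-count filter called the bipolar gene Scgn lower (adjusted p = 0.00244). The amacrine and horizontal medians were 0.37 and 0.50 without the library labelled cko a, and -0.21 and 0.08 without the library labelled cko b. The mean log2 difference of the amacrine list from the controls was -0.25 in cko a and 0.30 in cko b, and that of the horizontal list -0.11 and 0.59. The bipolar median was 0.04 without the library labelled cko a and -0.28 without cko b. The Muller glia median was -0.02 without control a and 0.23 without control b. The ganglion cell median was -0.14 without the library labelled cko a and -0.45 without control b. Without control b the ganglion cell list was called lower (adjusted p = 0.00875), as it was with no low-count filter (0.0435) and with the sex covariate (0.0484). The most abundant members were Tmem215 (log2 0.40), Calb2 (-0.26), Sept4 (0.17), Nefl (0.35) and Crym (-0.38). Reactive glia genes had a median of -0.29 (camera adjusted p = 0.137); it was -0.12 without control a, -0.51 without control b, -0.48 without the library labelled cko a, -0.17 without cko b and -0.01 with no low-count filter, and Nes was at 28.7 against 45.9 CPM.

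Among developmental lists, retinal progenitor genes had a median of -0.21 (camera adjusted p = 0.222). The list's mean log2 difference from the controls was -0.60 in the library labelled cko a and 0.17 in the library labelled cko b. Without the library labelled cko b, which leaves 1 library in that group, the list's median was -0.68, and without cko a it was 0.11. Without control c camera called the list lower at the preset correlation (median -0.34, adjusted p = 0.0452). The estimated correlation of its members over all 5 libraries was 0.40. The median was -0.10 without control b. Pax6 was at 344 CPM ± 0.602 (SD, n = 2) against 221 ± 44.1 (SD, n = 3; log2 0.64, SE 0.21; edgeR adjusted p = 0.433), opposite to the list's median. The neurogenic precursor list had a median of 0.00 and a mean of -0.07, with camera's direction downward (adjusted p = 0.749); the median was 0.10 without the library labelled cko a and -0.24 without cko b, and -0.02, 0.12 and -0.12 without control a, b and c. Otx2 was at 1181 against 857 CPM. The Notch list had a median of -0.00 and a mean of 0.00, with camera's direction upward (adjusted p = 0.983); the median was positive with upper-quartile factors (0.01) and library totals (0.07). The Notch median was 0.10 without the library labelled cko a, -0.42 without the library labelled cko b and 0.22 without control b.

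G2 and M phase genes were lower as a list: 21 of 25 had negative log2 values, the median was -0.25 (camera adjusted p = 0.0301; adjusted p = 0.756 with an estimated correlation), and 1 had an unadjusted p under 0.05. The mean log2 difference from the controls was -0.46 in the library labelled cko a and 0.00 in cko b, where single controls lay between -0.22 and 0.20. Top2a was at 91.3 against 109 CPM (log2 -0.25, SE 0.22). The call was lost without control b (median -0.18, adjusted p = 0.494) and without the library labelled cko a (median -0.09, adjusted p = 0.735), and the median was -0.45 without the library labelled cko b. The S phase list had a median of -0.12 (camera adjusted p = 0.362), which was -0.19 without control a, -0.07 without control b, -0.18 without control c and -0.19 without the library labelled cko b, with Mcm7 at 181 against 196 CPM.

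Integrated stress response genes, which respond to amino acid shortage and unfolded protein, were lower in both libraries labelled cko. Of 15 members 12 had negative log2 values, and the mean log2 difference from the controls was -0.40 in cko a and -0.29 in cko b. Nupr1 was the 1 member that fell when adjusted over the list alone, at 0.705 against 2.01 CPM (log2 -1.50, SE 0.36; edgeR adjusted p = 0.354 over all genes, and 0.0366 with no low-count filter). Atf4, the transcription factor of the response, was at 331 against 464 CPM (log2 -0.49, SE 0.25; edgeR adjusted p = 0.490). The list's median was -0.31 (camera adjusted p = 0.0130; adjusted p = 0.467 with an estimated correlation), and it was the 1 list that passed fry's directional test (adjusted p = 0.0371). The camera call was lost without control b (median -0.37, adjusted p = 0.0708).

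Interferon response genes were high in 1 library. The list's mean log2 difference from the controls was 1.40 in the library labelled cko b and -0.32 in the library labelled cko a. The median over both was 0.78 (camera adjusted p = 0.00442; adjusted p = 0.723 with an estimated correlation), and without the library labelled cko b it was -0.52 (adjusted p = 0.474). The call was also lost with the stricter low-count filter (median 0.69, adjusted p = 0.0783). Rtp4 was the 1 member that rose when adjusted over the list alone, at 0.394 and 2.50 CPM in cko a and b against 0.143 to 0.309 CPM; with no low-count filter edgeR called Rtp4 (adjusted p = 2.7e-05) and Usp18 (0.0254) over all genes.

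The p53 target list had a median of 0.31 (camera adjusted p = 0.0913). Eda2r, a tumour necrosis factor receptor family gene, rose when adjusted over the list alone, at 2.13 and 7.09 CPM in cko a and b against 0.686 to 0.972 CPM in the controls (log2 2.48, SE 0.47; edgeR adjusted p = 0.147 over all genes). DESeq2 called Eda2r over all genes (adjusted p = 0.00114, and 0.00053 on the genes kept for edgeR), and edgeR called it with no low-count filter. The log2 of Eda2r was 3.10 without the library labelled cko a. The p53 list was called higher by camera without control c (adjusted p = 0.0452). Its median was 0.33 without the library labelled cko a and 0.09 without the library labelled cko b. Its mean log2 difference from the controls was 0.01 in cko a and 0.42 in cko b. Microglia and macrophage genes had a median of 0.22 (camera adjusted p = 0.222) and were called higher without control c (adjusted p = 0.0470) and with the GC and length trend removed (0.0183). Without the library labelled cko a their median was 0.47. Their mean log2 difference from the controls was -0.25 in cko a and 0.46 in cko b, and the median was -0.13 without the library labelled cko b. Endothelium and pericyte genes had a median of -0.01 (camera adjusted p = 0.963), positive with upper-quartile factors (0.0014) and library totals (0.06), without control a (0.02) or b (0.11) and without the library labelled cko b (0.18). Astrocyte genes had a median of -0.17 (0.387), which was -0.27 without control c, -0.42 without the library labelled cko a and -0.30 without cko b. In the cone, reactive glia, progenitor, neurogenic, Notch, G2 and M phase, S phase, microglia, endothelium and astrocyte lists edgeR called 0 members over all genes and 0 when adjusted over the list alone, with 0, 3, 3, 1, 2, 1, 2, 0, 1 and 0 at an unadjusted p under 0.05; DESeq2 and limma-voom also called 0. With no low-count filter edgeR called Dapl1 of the progenitor, Kdr of the endothelium and Pax2 of the astrocyte list (adjusted p = 0.0446, 0.0256 and 0.0382). Kdr had a log2 of 0.83 with and without the filter. With the filter its edgeR unadjusted p was 0.0675 and its groups overlapped, so the unfiltered call reflects the fit and not a larger difference.

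**Figure D3:**
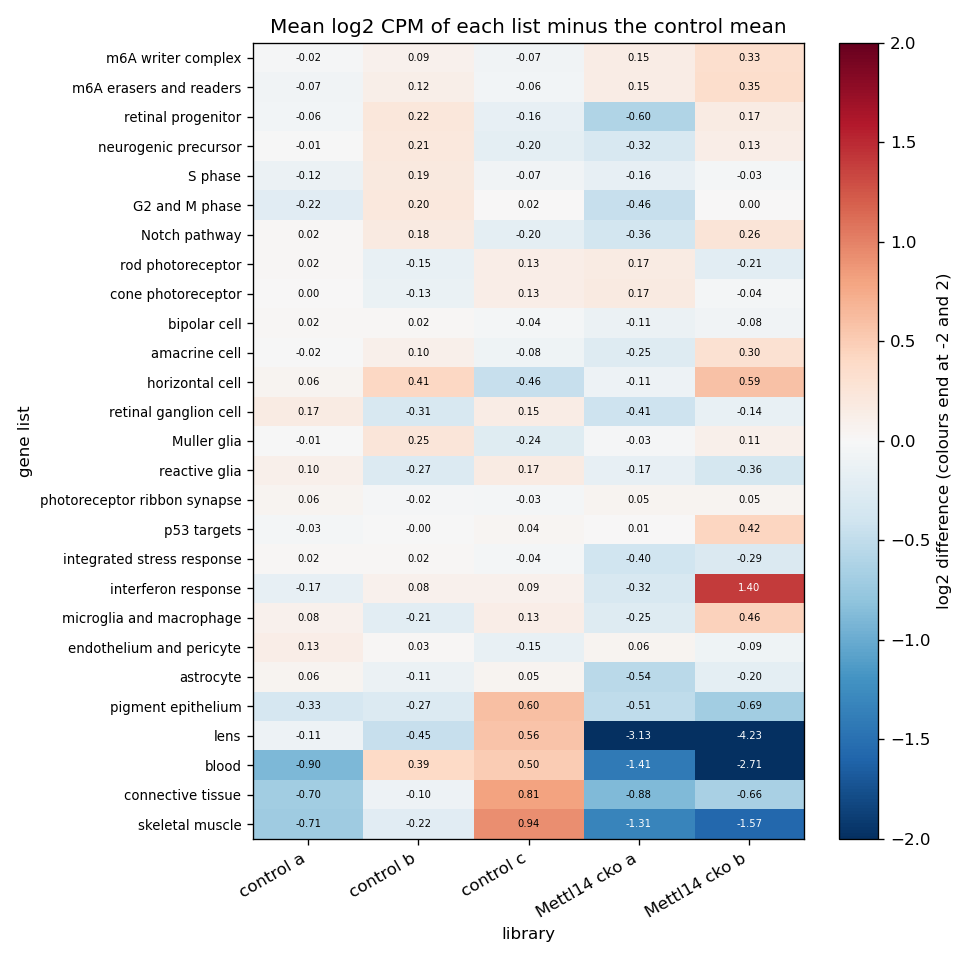
Mean log2 CPM of each of the 27 gene lists in each of the 5 libraries, minus the mean of the 3 controls; each cell prints its log2 value, and colours end at -2 and 2. The lens list reads -3.13 and -4.23 in the libraries labelled Mettl14 cko a and b, while the interferon list reads -0.32 in cko a and 1.40 in cko b.

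The libraries labelled cko were not more alike than libraries of different groups. Their log2 CPM correlated across genes at r = 0.977, against 0.964 to 0.983 between groups and 0.975 to 0.989 among the controls; genes are not independent replicates. The first principal component (45.0% of the variance) placed control c at one end (-53.9) and the library labelled cko b at the other (38.9), with cko a at 23.0. Mitochondrially encoded genes held 4.38% of the counts in control c and 2.65% to 3.41% in the other libraries, and ribosomal protein genes 6.05% against 3.70% to 5.01%. By Xist and Y-linked genes, control a, control b and cko a read as female, and control c and cko b as male. At an unadjusted p under 0.05 edgeR found 928 genes higher and 913 lower, where chance alone gives 852 in all; 2 of the other 9 splits of the libraries into 3 and 2 gave more than the 1841 of the labelled groups, with 3476 and 1859. The groups did not overlap for 29.4% of genes, where chance gives 20%.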

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

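DESeq2 on the genes kept for edgeR, the sex covariate, the removal of other tissues' genes and the removal of the GC and length trend were chosen after seeing the data; the cause of the changes below was not tested unless given. The 17 calls (1 higher, 16 lower) were also 17 with DESeq2's or upper-quartile size factors. With library totals there were 11 (0 higher; 11 with an absolute log2 of at least 1), and at an adjusted p under 0.01 also 11 (0 higher; 11 large). Without a low-count filter there were 262 (111 higher, 151 lower, 186 large; 21 of them lens list or crystallin genes), DESeq2 with its own filtering, which changes the genes tested as well as the test, called 85 (30 higher, 55 lower, 67 large), and DESeq2 on the genes kept for edgeR 91 (35 higher, 56 lower, 76 large); all 3 included the 17. The filter at 1 CPM and limma-voom called 0 higher (1656 and 1895 genes at an unadjusted p under 0.05). With the sex covariate 9 genes were called (0 higher, 9 lower, 9 large), and with the GC and length trend removed 21 (5 higher). With other tissues' genes removed edgeR called 0 genes, 0 higher, 0 lower and 0 large (1820 unadjusted), and 4 of the 19 lists left to test; for BC030499 the loss follows from the adjustment, as its log2 was kept. Leaving out each library gave 0 to 45 calls, 0 to 19 higher, 0 to 26 lower and 0 to 45 large: 0 without cko b (2210 unadjusted), where, as without cko a, the lone cko library is assumed to vary like the controls, and 45 without control b; calls higher were 8 without cko a and 0 without control c. The letters of the titles are not said to pair libraries, and same-letter libraries deviated from their group means with r = -0.00676 (a) and 0.149 (b). The replicate block gave 39 calls (13 higher, 26 lower, 38 large). They included the Y-linked Kdm5d, Eif2s3y, Uty and Ddx3y, as control b read as female and cko b as male. Control c has no cko library of its letter, so it adds nothing to that contrast. Under the block camera no longer called the writer and connective tissue lists (adjusted p = 0.0693 for both). It called the progenitor list lower (0.0128) and the p53 list higher (0.0446). Camera called 10 lists, 0 with an estimated correlation, and fry called 1. Leaving out 1 library moved the rod list's median from -0.23 (without cko a, called the other way) to 0.21 (without cko b), and the interferon list's from -0.52 (without cko b, reversed) to 1.42 (without cko a). The log2 of Mettl14 stayed between 0.08 (without cko a) and 0.39 (without cko b), never past the threshold. Of 705 values of 40 other named genes under alternatives, 681 kept their side of the threshold, 17 lost and 7 gained a call, and 0 reversed; of 478 list values 418 kept it, 42 lost and 16 gained a call, and 2 reversed. Scaling by library totals moved the median of all genes to 0.05. At this depth and number of libraries edgeR recovered 43.6% of simulated 2-fold changes in genes with a mean of at least 1 CPM.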

Other observations

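DESeq2 with its own filtering (26716 genes with a p, against 17039 tested by edgeR) called 85 genes on the same 5 libraries, and 59 of them belonged neither to the lens and crystallin genes nor to another check list; 30 of the 59 were higher in the libraries labelled cko and 29 lower. All 59 had an edgeR unadjusted p under 0.05, and BC030499 was the 1 that edgeR also called. Ccnl2, a cyclin tied to splicing, was at 335 and 358 CPM in cko a and b against 152 to 189 CPM in the controls (DESeq2 log2 1.02; edgeR adjusted p = 0.147). The telomere protein gene Terf2ip (log2 1.15), the photoreceptor guanylate cyclase Gucy2f (0.97) and Ythdf2 (0.89) were on the same side. Lower were the immediate-early genes Jun (log2 -0.91) and Junb (-1.10), the MAP kinase phosphatase gene Dusp8 (-0.90) and the synuclein gene Sncb (-1.03). The check lists hold only some genes of each tissue, so whether the 29 lower genes came from the retina was not tested. Some were highest in control c, as the lens, pigment epithelium and connective tissue lists were. Col8a2 was at 15.73, 17.04 and 43.34 CPM in control a, b and c, and Mfrp at 12.99, 12.14 and 27.17 CPM. Others were not, among them Dusp8 at 278, 227.7 and 260.8 CPM. On the genes kept for edgeR, a run chosen after seeing the data, DESeq2 called 91 genes, 56 of these 59 among them, and every gene named here. These genes were picked after their values were seen, and in data simulated on those kept genes 10.9% of DESeq2's calls were false.

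All tests below except that of m6A motifs were chosen only after the result was seen. The fall of 15 lens list genes could come from less lens tissue carried into the libraries labelled cko. The 7 lens list members tested that are not crystallins had a median log2 of -2.49, and 6 of them were below -1, which argues against lower crystallin expression in the retina alone. The crystallins, however, had a median of -4.48, and the means of both parts of the list differed by 2.06 (SE 0.50). That SE is over list members, which are not independent replicates, and Bfsp1, not a crystallin, fell about as far as they did (-4.35). Less lens tissue alone would lower both parts by a like fold unless other cells also express the less affected genes, which was not tested. The lowest control lens share was 9.43 times the highest cko share, while the controls differed among themselves by 2.04 times. So less lens tissue stays open, and a lens or a lens attachment altered by the genotype cannot be told apart from a difference in dissection, because both follow the same 2 groups. The blood, skeletal muscle and pigment epithelium lists were lower too (medians -1.93, -1.50 and -0.68), while the endothelium and pericyte median was -0.01. A change confined to the lens does not cover those lower lists, and whether they share a cause with the lens genes was not tested.

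Mettl14 was not lower in the libraries labelled cko. A swap between a control and a cko library would show as a control low in Mettl14 only if the deletion lowers the count. The lowest library, control c, held 0.846 of the median of the others, so no library was low in Mettl14 under either label. That cannot decide whether libraries were swapped. A deletion that removes m6A without lowering the gene count remains possible; m6A marks DRACH motifs far from exon junctions and speeds decay, so its loss predicts higher levels of genes rich in such motifs. Across 14447 genes the partial rank correlation of log2 fold change with far motifs, given GC content, length and other gene features, was 0.0822, above the highest of the other 9 splits of the libraries (0.0417), as set out before the result was seen; other splits reached -0.0695 and -0.0667, close to it in size. Without that adjustment the rank correlation of log2 fold change was 0.270 with far motifs, 0.332 with length and -0.321 with GC content. The split of control b and cko b from the others gave 0.281 with far motifs and 0.465 with length. How much of these trends the adjustment leaves was not tested. In 4 groups of genes by far motifs given the same features, poorest to richest, the median log2 was -0.071, 0.008, 0.015 and 0.004. Only the poorest group stood apart, so the correlation was not a steady rise with motifs. The same motif read backwards gave 0.035 in the labelled groups. By library against the controls it gave 0.055 in cko a and 0.005 in cko b, where far motifs gave 0.064 and 0.068. That 10 splits are too few for a share under 0.05 was weighed only afterwards, and genes are not independent replicates, so the question stays open.

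The interferon list may be high in the library labelled cko b for a reason of that library. The list's mean in cko a, -0.32 relative to the controls, is part of how the pattern was seen and is 1 library, so an effect of the genotype stays open. Whether more microglia or macrophages alone account for it is not settled. In cko b the interferon list rose by 0.937 more (SE 0.243) than the microglia and macrophage list. That SE is over list members of 1 library, whose estimated correlations were 0.57 and 0.53, so it is too small to decide. An infection or another difference between animals was not tested. For the 17 genes called between the groups, 1 of the 10 splits of the 5 libraries into 3 and 2, the real one, gave as many; the highest other split gave 7, and 10 splits are too few for a share under 0.05.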
